A study of Caenorhabditis elegans with 2 samples.

How the data were processed

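Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed against AMA-1, the large subunit of RNA polymerase II, in whole L2 larvae of both sexes of the C. elegans wild-type strain N2. The labels give 1 group with 2 biological replicates and no second condition, stage or genotype. No test between groups was therefore made, and no paired analysis applies. Values per replicate are printed without an SD, because 2 lists from separate peak calls give no spread on a common scale.

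The deposited files are peak lists in the narrowPeak layout. Per the deposited file descriptions, each replicate list was derived from that replicate's alignment together with a file from which the control-normalised signal track was also derived. The pooled list was derived in the same way from both alignments, and the optimal list from both replicate lists and the pooled list by the irreproducible discovery rate (IDR). Each list was deposited on the ce10 and the ce11 build. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here. The authors gave each peak a signal value (column 7, never negative), whose scale is not given in the sources used here. It ranks and describes peaks within a list. Column 10 gives the summit. The replicate and pooled lists each end at exactly 30000 peaks and hold background as well as enriched regions. Only their upper part was used as peaks, except where whole replicate lists are named and where replicate signals were compared. Read depth is not given in the files and is unknown here. Wilson 95% intervals on shares therefore cover counting error over peaks or genes only, and neighbouring genes or peaks are not independent.

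Positions were read on ce11, whose chromosome lengths hold every deposited peak end, against the WBcel235 sequence and the Ensembl release 115 annotation with 19973 nuclear protein-coding genes. RefSeq gene names were used for let-7. The ce10 lists were used only for counts, signal values and the correlation between replicates, and no coordinate was converted between builds. The optimal list held 1861 peaks on ce11 and 1957 on ce10. In both builds it was exactly the part of the pooled list with the highest signal, so that taking that many pooled peaks instead gave the same list. Where a replicate was used alone, its 1861 peaks of highest signal were taken. No column of per-sample values was left unmapped.

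Each summit was placed, in this order, within 500 bp of a protein-coding 5′ end, in a gene body, within 500 bp past a 3′ end, or elsewhere. The shares were compared with 1000 circular shifts of all summits along their chromosomes (two-sided permutation test, smallest possible p 0.001). A gene was called occupied where a summit lay within 500 bp of its annotated 5′ end. Annotated 5′ ends of trans-spliced C. elegans genes can lie downstream of the start of transcription, and a summit between divergent genes counts for each of them. Occupied members of 26 gene lists were counted against all other protein-coding genes with Fisher's exact test (two-sided, Benjamini-Hochberg over the 26 lists). The lists were ribosomal proteins, translation factors, histones, cuticle collagens, molting and epidermis, muscle, intestine, neurons, germline, vitellogenins, sperm, inducible heat shock, constitutive chaperones, proteasome, V-ATPase, oxidative phosphorylation, glycolysis, RNA polymerase II and transcription, DNA replication and cell cycle, heterochronic genes, chemoreceptors, F-box and BTB-MATH genes, C-type lectins, lysozymes and antimicrobial peptides, nuclear hormone receptors and homeobox factors. Of 489 symbols in the lists written as symbols, 471 matched a protein-coding gene. The tissue lists stand for the cell types of a whole animal.

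The median signal of the occupied members of a list was compared with random draws from all occupied genes (two-sided permutation test, 100000 resamples, lists with at least 5 occupied members). Fisher's exact test was used for X against autosomes, for the middle against the outer parts of autosomes (each chromosome's central 50 percent of length against the rest) and for 7 classes of noncoding genes against protein-coding genes. GC content within 100 bp of summits was compared with windows 1000 bp to each side (sign-flip permutation test, smallest possible p 1e-05). The motifs TATAAA, GAGAGA, GGGCGG, TTTCAG and TTTTTT were compared with the window 1000 bp further along the plus strand (exact McNemar test, two-sided). Gene orientation was not considered in this. Replicates were compared through log2(replicate 1 signal / replicate 2 signal) at optimal peaks overlapped in both replicates, centred on its median. Because the lists come from separate peak calls, only a list's position relative to other genes is described, as the percentile of its median among 10000 random lists of the same size matched on mean signal. No test was made of it, since each side is 1 library.

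The choices above were made before the data were examined. The genes named were fixed then too. They were the nearest 5′ end within 1000 bp of each of the 25 optimal peaks of highest signal, the 4 members with the highest promoter signal in each list that passed its test and 2 in each list that did not, the 5 genes at either end of the replicate ratio, ama-1 and all heterochronic genes. Other genes named were chosen after their values were seen, among them the noncoding genes and the members of the whole-gene comparison.

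Other settings, chosen before the data were examined, were the 930 optimal peaks of highest signal, each replicate alone, windows of 250 bp either side or of 1000 bp upstream to 200 bp downstream, the whole gene, overlap of the interval, the nearest 5′ end only, genes with no other 5′ end within 1000 bp, other overlap rules, flanks at 500 bp, removal of a lowess trend and the ce10 lists. Chosen after seeing the data were 3′ ends, summits in heat shock gene bodies or past their 3′ ends, the 200 peaks of highest signal in each replicate, windows in which at least 90 percent of 32-mers occur once in the genome, noncoding genes without a protein-coding 5′ end within 1000 bp, whole-gene occupancy per replicate, also against 10000 random lists matched on gene length, and a whole-gene replicate comparison. The last took, in each replicate's 30000 peaks, the highest signal from 500 bp upstream to 500 bp past the 3′ end, with lists matched on signal or on gene length, ranks within each list in place of signal, each pair of peaks counted a single time, or unique windows only. In all, 654 alternative values were computed.

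Each procedure was tested on simulated data. After circular shifts of the peaks, 5 of 1300 list tests on 19973 genes were called. A planted list of 200 genes was called in 20 of 50 trials at an odds ratio of 2.11 and in 50 of 50 at 4.75. A planted 40-gene signal factor of 2 among 959 occupied genes was found in 10 of 10 trials, and an unchanged list was called in 1 of 10. A planted log2 shift of 1 in 40 of 7000 genes was found in 50 of 50 trials, and an unchanged list lay outside the central 95 percent in 1 of 50. Of 200 summits moved onto 5′ ends, 170 appeared as excess over the shifted mean, and all 200 windows given GAGAGA were counted. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.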

Results

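The data map where RNA polymerase II lies along the genome of C. elegans larvae in the L2 stage, the stage between the first and the second larval molts. AMA-1 is the large, catalytic subunit of RNA polymerase II, which transcribes messenger RNAs and many small nuclear RNAs, and its ChIP-seq signal marks where the enzyme sits on chromatin. The series holds 1 group of 2 biological replicates of whole wild-type N2 larvae, each a mixture of all tissues. No other stage, treatment or genotype stands beside them, so the comparisons are between groups of genes, between parts of the genome and between the replicates. Read depth is unknown from the deposited lists. Positions are on ce11 (WBcel235), and signal is the authors' own value per peak.

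Among the strongest AMA-1 peaks were several at small RNA genes and several past the 3′ ends of heat shock and chaperone genes, a grouping made after seeing the peaks and not tested. The peak of highest signal (1434.88) had its summit at chromosome I position 4172339, beside a gene for SL2 RNA, sls-2.4 (4172206 to 4172315), and at -750 bp from the 5′ end of egg-5. SL2 RNA is the spliced leader that is joined to messages of downstream operon genes. The summits ranked next were inside sls-2.2 on chromosome II (signal 1416.63, summit 5543693) and inside sls-2.1 on chromosome II (1269.83, summit 5844963). The sls-2.1 summit lay 578 bp downstream of the annotated 5′ end of ZK1248.17 and past the 3′ end of that gene. A further SL2 gene, sls-2.8, held the summit nearest to the 5′ end of Y75B8A.23 (504.1). Of the 25 peaks of highest signal, 4 had an sls-2 gene within 500 bp, 7 had a gene of the snRNA class, and 10 had the 3′ end of a protein-coding gene. A protein-coding 5′ end within 1000 bp named 14 of them and 11 have a position only.

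Among the protein-coding genes at these peaks, mdt-26, which encodes a subunit of the Mediator complex, had a peak 84 bp after its 5′ end in a coding exon (657.5) and another 647 bp after it in an intron (414.6). The peak 205 bp upstream of ufbp-1 (594.0) lay 98 bp past the 3′ end of hsp-110, a chaperone gene of the HSP70 superfamily. A peak 58 bp after the 5′ end of tos-1 reached 593.7. Peaks lay 55 bp past the 3′ end of F44E5.5 (580.7), past that of F44E5.4 (417.6) and 82 bp past that of hsp-1 (484.4), all HSP70 family genes. Others lay 1 bp past the 3′ end of the small heat shock gene hsp-12.3 (426.2), beside the snRNA gene F38E11.11 (9444642 to 9444763), and 114 bp past that of the DnaJ co-chaperone gene dnj-13, where F54D5.7 starts (349.4). The remaining named genes were ikke-1 (481.6), T28F4.5 (418.6), the cathepsin gene cpz-1 (373.9), the autophagy gene lgg-1 (357.8) and mig-38 (349.5). The ikke-1 summit lay at -749 bp from its 5′ end, just past the 3′ end of R107.5, and the lgg-1 summit at -755 bp. The cpz-1 summit lay in a coding exon of cpz-1, beside the snRNA gene F32B5.9. Peaks with a position only included 1 at the microRNA gene cel-mir-52 on chromosome IV (1032.89, summit 14033992), 1 in the noncoding gene tts-1 on the X chromosome (635.9) and 3 in the noncoding gene C30E1.9, with the highest at 1050.29. Of the 25 peaks, 24 had a higher signal in replicate 1 than in replicate 2, whose signal scales are not known to be equal. F44E5.4 and F44E5.5 are near-identical copies, and only 0.261 of the promoter window of each is unique. The uniqueness of the sequence under their peaks past the 3′ ends is not given here, so the reads there may be uncertain.

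**Figure D1:**
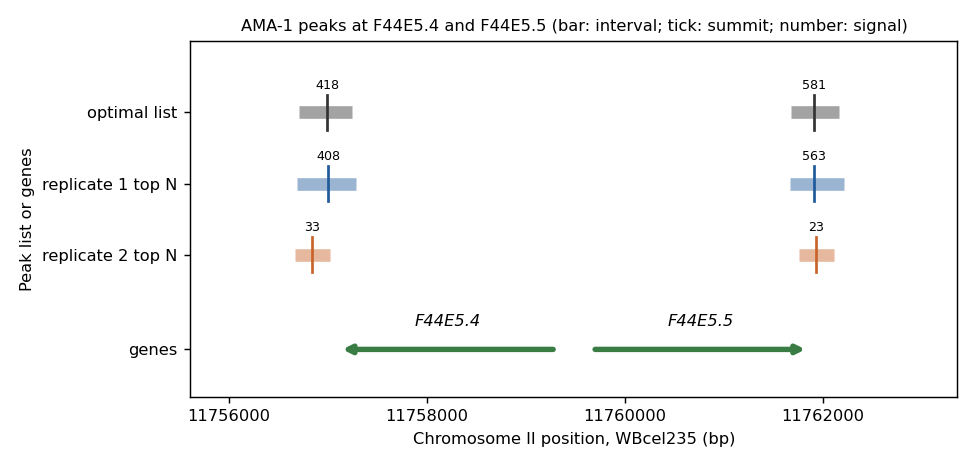
AMA-1 peaks at the HSP70 genes F44E5.4 and F44E5.5 on chromosome II (x axis, bp on WBcel235) in the optimal list and in the 1861 peaks of highest signal of each replicate, with bars for intervals, ticks for summits and numbers for the signal. The summits lie just past both 3′ ends, with a signal of 562.7 in replicate 1 and 23.3 in replicate 2 past F44E5.5.

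The replicates shared many but not most of their strongest peaks. Of the 1861 peaks of highest signal in replicate 1, 41.7% (95% interval 39.5 to 43.95%) were overlapped by 1 of the 1861 in replicate 2, and 41.5% in reverse. After 200 circular shifts the overlap averaged 1.32% and reached 1.99% at most. The optimal list held 1861 peaks with a median width of 370 bp. It was overlapped at 81.5% of its peaks by the strongest peaks of replicate 1 and at 56.0% by those of replicate 2. Over the whole replicate lists these shares were 98.8% and 95.7%. The median signal of the 1861 strongest peaks was 49.3 in replicate 1 and 26.05 in replicate 2, and the highest 1033.13 and 476.4. At the 1759 optimal peaks found in both whole lists, the log2 signals had a Spearman rho of 0.12 (bootstrap 95% interval 0.07 to 0.17) and a Pearson r of 0.28 across peaks, which are not independent replicates. Optimal peaks were taken from the top of the pooled list, so these values do not describe the whole range of signals. With an overlap of 50 percent in both directions 29.3% of the replicate 1 peaks were shared, and with summits within 100 bp 28.5%.

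Optimal AMA-1 summits gathered at both ends of genes and were fewer inside them. Of the 1861 optimal summits, 837 (44.98%, 95% interval 42.7 to 47.2%) lay within 500 bp of a protein-coding 5′ end, against 18.9% on average after shifting (permutation p = 0.001, the smallest possible). Another 188 (10.1%) lay within 500 bp past a 3′ end, against 4.14%, while 533 (28.6%) lay in gene bodies, against 52.2%, and 303 (16.3%) lay elsewhere, against 24.7% (each permutation p = 0.001). Counted without regard to 5′ ends, 33.1% lay within 500 bp of a 3′ end and the highest of the shifts gave 20.3%, a comparison chosen after seeing the data. The replicates differed in these shares. Replicate 1 alone had 48.5% of its summits at 5′ ends and 26.9% in gene bodies, whereas replicate 2 alone had 30.1% at 5′ ends and 45.8% in gene bodies. Exonic gene-body summits were 13.6% of the optimal list, against 22.8% after shifting (permutation p = 0.001), but 25.31% in replicate 2 alone, against 22.8% (permutation p = 0.036). The gene-body difference was 18.9 percentage points (95% interval 15.9 to 21.9, Fisher's exact test p = 3.13e-33), a test over summits in 1 library per side.

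**Figure D2:**
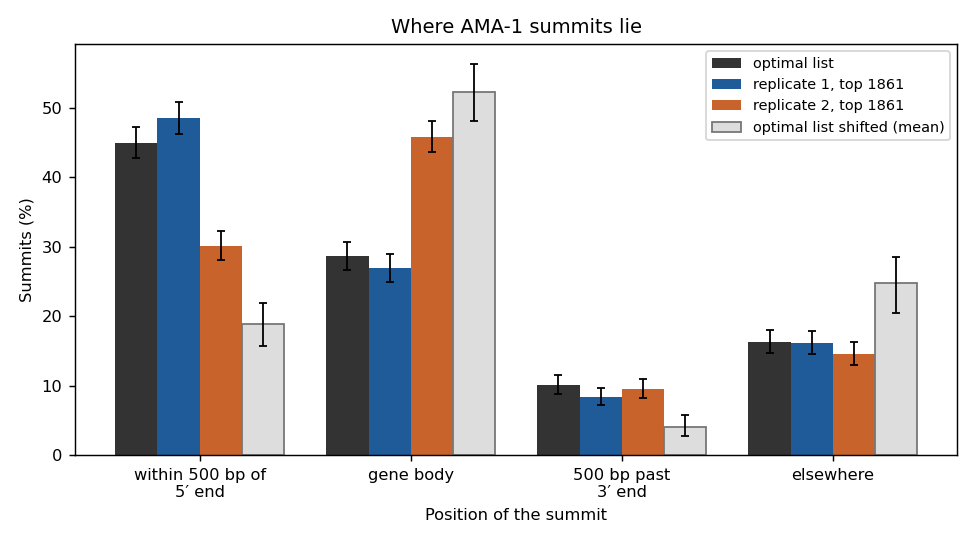
Share of AMA-1 summits (y axis, percent) by position (x axis) for the optimal list and for the 1861 peaks of highest signal of each replicate, with Wilson 95% intervals, and for the shifted optimal list, with the mean and range over 1000 shifts. Replicate 2 has 45.8% of its summits in gene bodies against 26.9% in replicate 1.

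Constitutive chaperone, ribosomal protein and V-ATPase genes had the highest shares with AMA-1 at their 5′ ends among the 26 lists in the optimal list with 500 bp windows. An optimal summit lay in the promoter window of 959 of 19973 protein-coding genes (4.80%, 95% interval 4.51 to 5.11%). Among ribosomal protein genes it did so in 45 of 79 (57.0%), an odds ratio of 27.5 against all other genes (Fisher's exact test, adjusted p = 2.34e-37). They were led by rpl-20 (signal 186.5, summit at -278 bp from the 5′ end, chromosome IV position 4750056), rpl-3 (174.9), rps-26 (167.0) and rpl-35 (161.0). Genes on the constitutive chaperone list were occupied in 16 of 25 (64%, odds ratio 35.8, exact adjusted p = 8.32e-15). The highest were hsp-110 (199.1), hsp-1 (151.8), dnj-13 (118.9) and hsp-90 (106.0). Whether stress also induces members of this list was not examined here. The V-ATPase, the proton pump of lysosomes and other compartments, had 9 of 21 subunit genes occupied (odds ratio 15, exact adjusted p = 1.48e-06), among them vha-8 (96.99), vha-1 (92.9), vha-12 (75.1) and vha-11 (69.5). The shares depended on the replicate and the window. In replicate 1 alone 52 of 79 ribosomal protein, 17 of 25 chaperone and 11 of 21 V-ATPase genes were occupied (odds ratios 36.6, 39.1 and 20.1), and in replicate 2 alone 16, 8 and 3 (8.59, 15.7 and 5.53). With 250 bp windows the counts were 16, 8 and 5 (odds ratios 7.44, 13.6 and 9.02), and heat shock genes then had the highest share (36.4%).

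Several housekeeping lists passed the same test with smaller shares. Proteasome genes were occupied in 8 of 33 (odds ratio 6.39, exact adjusted p = 0.000484), with rpn-3 (199.1), pbs-1 (83.2), rpt-2 (81.7) and pbs-3 (71.4) highest, and rpn-3 shared its summit with the divergent hsp-110. Oxidative phosphorylation genes were occupied in 9 of 40 (odds ratio 5.80, exact adjusted p = 0.000403). Among them were cox-5A (108.2) of the cytochrome oxidase, cyc-1 (74.9) of complex III, and atp-2 (85.7) and atp-1 (74.8) of the ATP synthase. Translation factors were occupied in 8 of 36 (odds ratio 5.70, exact adjusted p = 0.000722). The elongation factor genes eef-1A.1 (131.5) and eef-1A.2 (109.1), iff-2 (124.4), which encodes an eIF5A, and ife-3 (119.8), which encodes an eIF4E, stood highest. Glycolysis genes were occupied in 6 of 21 (odds ratio 7.97, exact adjusted p = 0.000914), led by the aldolase gene aldo-2 (111.7), the GAPDH genes gpd-3 (84.8) and gpd-2 (73.8), and gpi-1 (55.1). Genes of RNA polymerase II and its cofactors were occupied in 8 of 44 (odds ratio 4.43, exact adjusted p = 0.00246), with mdt-26 (657.5), taf-4 (235.8), rpb-11 (71.1) and the cyclin T gene cit-1.1 (67.3) highest. ama-1 itself (chromosome IV, 4248070 to 4258169) had no optimal summit from 500 bp upstream of its 5′ end to its 3′ end. Between the replicates alone the odds ratio was 4.58 to 9.13 for the proteasome and 4.75 to 8.81 for oxidative phosphorylation. In replicate 2 alone the odds ratio of the polymerase list was 2.42 (exact adjusted p = 0.225, range 0.000171 to 1 over its alternatives), and among genes with no other 5′ end within 1000 bp it was 0. The glycolysis call was lost with windows of 250 bp (exact adjusted p = 0.0599), with 1000 bp upstream to 200 bp downstream (0.191) and with unique windows (0.0917; range 8.2e-05 to 0.191), and that of translation factors among genes with no other 5′ end within 1000 bp (0.190; range 5.13e-06 to 0.190).

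**Figure D3:**
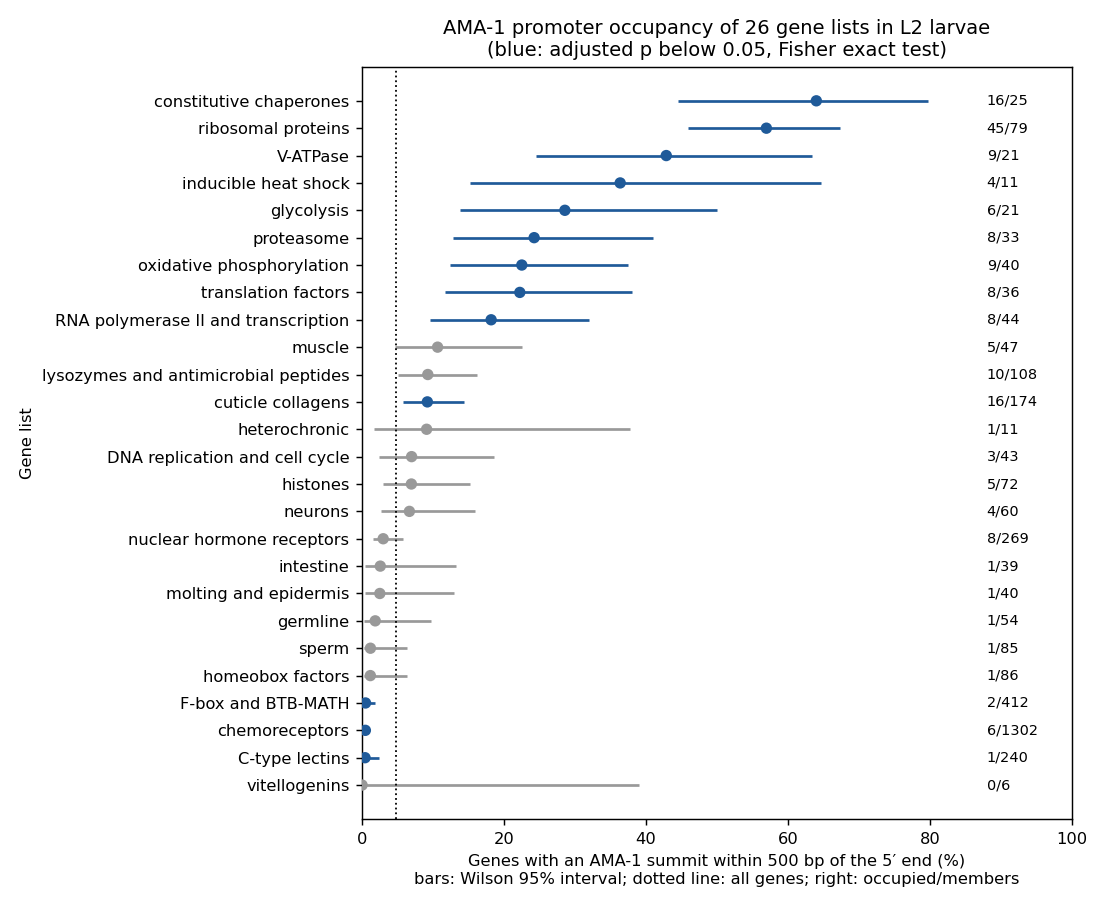
Share of genes with an optimal AMA-1 summit within 500 bp of the 5′ end (x axis, percent) in 26 gene lists (y axis), with Wilson 95% intervals, occupied and total members at the right, and the share of all protein-coding genes as a dotted line. Constitutive chaperones (64%) and ribosomal proteins (57.0%) lie highest, and chemoreceptors (0.461%) are among the lowest.

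Genes on the inducible heat shock list, several of which are transcribed strongly after proteotoxic stress, were occupied although the labels name no heat treatment. The list also holds genes, such as dnj-12, whose induction by heat was not examined here. A summit lay at 4 of 11 (36.4%, 95% interval 15.2 to 64.6%, odds ratio 11.4, Fisher's exact test, adjusted p = 0.00288). hsp-16.2 and hsp-16.41, divergent small heat shock genes on chromosome V, shared a summit (235.8, position 1804836). The others were hsp-70 (88.4, 85 bp after its 5′ end) and the DnaJ gene dnj-12 (66.7). In replicate 2 alone the odds ratio was 7.36 (exact adjusted p = 0.0796), and among genes with no other 5′ end within 1000 bp the adjusted p was 0.230 (range 3.04e-05 to 0.230 over the alternatives). hsp-16.1 and hsp-16.48 had no unique sequence in their promoter windows, so their promoter calls are uncertain.

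Cuticle collagen genes, which are expressed in waves around each molt, were occupied in 16 of 174 (9.20%, odds ratio 2.02, Fisher's exact test, adjusted p = 0.0232). The highest were col-166 (168.4), col-103 (166.1), col-10 (138.1) and col-107 (122.8). This call rested on replicate 2. There 18 of 174 were occupied (odds ratio 3.90, exact adjusted p = 2.56e-05), and in replicate 1 alone 9 of 174 (odds ratio 0.987, adjusted p = 1). It was also lost with 1000 bp upstream to 200 bp downstream (exact adjusted p = 0.210), over whole genes (0.103) and in unique windows (0.135; range 2.56e-05 to 1 over the alternatives).

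Lists with roles in particular tissues or at other ages were not called different from the rest by this test. They are smaller than the planted list of 200 genes, which was called in 20 of 50 trials at an odds ratio of 2.11. A difference in either direction could therefore be missed in them. The counts were 5 of 47 for muscle (exact adjusted p = 0.128), led by the actin gene act-4 (206.0) and the myosin light chain gene mlc-3 (62.9), and 4 of 60 for neurons (0.605), with ric-19 (53.4) and pgal-1 (53.3). Intestine had 1 of 39 (cpr-4, 52.7; exact adjusted p = 1), molting and epidermis 1 of 40 (pdi-2, 109.4; 1), germline 1 of 54 (syp-4, 63.4; 0.605) and sperm 1 of 85 (spe-5, 65.5; 0.281). Vitellogenins, the yolk proteins of adults, had 0 of 6 (exact adjusted p = 1). Unique windows made up 45.9% for sperm and 50% for vitellogenins, so these low counts are uncertain. Histones had 5 of 72 (exact adjusted p = 0.543), with the H3.3 gene his-72 (162.5) and the H4 gene his-37 (124.4) highest. Only 13.9% of histone windows are unique, and among those the odds ratio was 17.99 (exact adjusted p = 0.000359, range 0.000359 to 0.835 over the alternatives). Histones also passed in replicate 2 alone (7 of 72, odds ratio 3.59, exact adjusted p = 0.0168) and among genes with no other 5′ end within 1000 bp (27.8, 0.00255). Cell cycle genes had 3 of 43 (0.571), among them mdf-1 (63.2) and pcn-1 (61.2). Lysozymes and antimicrobial peptides had 10 of 108 (0.0736), with nlp-33 (169.9) and cnc-4 (94.7) highest. They passed with 250 bp windows (exact adjusted p = 0.0215) and with the nearest 5′ end only (0.0213; range 0.0213 to 0.426). The muscle list passed in replicate 1 alone (odds ratio 3.18, exact adjusted p = 0.0213) and among genes with no other 5′ end within 1000 bp (3.66, 0.0390; range 0.0213 to 1).

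Of the heterochronic genes, which time larval cell fates, 1 of 11 was occupied (exact adjusted p = 0.543). This was lin-66 (72.7, summit 97 bp upstream at chromosome IV position 13887982). daf-12 and lin-14 had an optimal summit only inside the gene (58.2 and 69.2). lin-28, lin-29, lin-41, lin-42, lin-46, hbl-1, kin-20 and nhr-85 had none from 500 bp upstream to the 3′ end. The microRNA genes lin-4, let-7, mir-48, mir-84 and mir-241 were not occupied. A summit of 52.9 lay beside the 3′ end of let-7 on chromosome X, 1870 bp from its 5′ end.

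Chemoreceptor, F-box and C-type lectin genes had AMA-1 at their 5′ ends less often than other genes. Chemoreceptors, which are expressed in a few neurons each, were occupied in 6 of 1302 (0.461%, odds ratio 0.0861, exact adjusted p = 7.78e-20). The highest were srh-2 (162.5), srh-269 (131.8), srbc-58 (81.3) and srh-16 (60.2), and the summit near srh-2 lay in the untranslated region of icl-1. F-box and BTB-MATH genes were occupied in 2 of 412 (odds ratio 0.0948, exact adjusted p = 2.91e-06), fbxb-72 (283.3) and fbxb-85 (63.4), and the summit near fbxb-72 lay 146 bp past the 3′ end of icl-1. In replicate 1 alone the F-box odds ratio was 0.219. C-type lectins were occupied in 1 of 240 (clec-1, 104.8; odds ratio 0.0820, exact adjusted p = 0.000607). With the 930 peaks of highest signal the lectin call was lost (odds ratio 0.166, exact adjusted p = 0.0667, range 0.000152 to 0.0667). Nuclear hormone receptors had 8 of 269 (exact adjusted p = 0.281), with nhr-88 (84.0) and nhr-49 (83.1) highest, and homeobox factors 1 of 86 (ceh-38, 82.8; adjusted p = 0.213).

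The median promoter signal of all occupied genes was 65.9. It was 82.4 in the 45 occupied ribosomal protein genes (ratio 1.25, permutation test, adjusted p = 0.0227 over 14 lists) and 48.7 in the 8 occupied nuclear hormone receptor genes (ratio 0.739, permutation adjusted p = 0.00056). The lowest signal in the optimal list was 47.4, so the receptor median lay just above the cut-off of that list. Translation factors stood at 103.96 (ratio 1.58, permutation adjusted p = 0.0760), and the other 11 lists had adjusted p-values from 0.491 to 0.996 and ratios from 0.919 to 1.38. The ribosomal protein call was lost in 6 of 8 alternatives (permutation adjusted p from 0.0123 to 0.628) and the receptor call in each replicate alone (ratios 0.997 and 0.854) and over whole genes (0.883; adjusted p from 0.0008 to 0.888). Collagens had a ratio of 1.05 in the optimal list, 1.44 in replicate 2 alone (permutation adjusted p = 0.0376, range 0.0376 to 0.997) and 1.47 in replicate 1 alone (permutation adjusted p = 0.188). Inducible heat shock genes had at least 5 occupied members only when any overlap of the interval counted, and there 6 genes had a median of 223.8 (ratio 3.38, permutation adjusted p = 0.00105). That p-value counts hsp-16.2 and hsp-16.41 separately, although they share a peak, and includes hsp-16.48, whose window is not unique. hsp-16.48 (211.7) and hsp-12.3 (426.2, beside an snRNA gene) counted only through the interval, with summits past their 3′ ends. With each of the 5 peaks counted once the median was 211.7 (ratio 3.19), the hsp-16.48 peak itself, which was not tested. Members with a summit in the promoter window had signals of 235.8 (hsp-16.2 and hsp-16.41), 88.4 (hsp-70) and 66.7 (dnj-12).

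Occupied genes were less frequent on the X chromosome and more frequent in the middle of autosomes. On X 90 of 2731 genes were occupied (3.30%), against 869 of 17242 on autosomes (5.04%, odds ratio 0.642, Fisher's exact test p = 4.07e-05). Among autosomes the share was 7.77% on III, 6.29% on I, 4.54% on IV, 4.29% on II and 3.72% on V. In the central part of autosomes 577 of 9597 genes were occupied (6.01%), against 292 of 7645 in the outer parts (3.82%, odds ratio 1.61, Fisher's exact test p = 3.9e-11).

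Genes for small nuclear, small nucleolar and microRNAs carried AMA-1 more often than protein-coding genes, and tRNA genes did not. Genes of the snRNA class, which holds the SL2 RNA genes, were occupied in 28 of 129 (21.7%, odds ratio 5.50, Fisher's exact test, adjusted p = 8e-11 over 7 classes), with a median signal of 148.6. The snoRNA class had 56 of 346 (16.19%, odds ratio 3.83, exact adjusted p = 3.92e-14), with F01D5.12 (341.6) and W06H8.17 (337.6) highest. The microRNA class had 30 of 261 (11.5%, odds ratio 2.57, exact adjusted p = 3.42e-05), led by cel-mir-52 (1032.89), the cluster of cel-mir-54, cel-mir-55 and cel-mir-56 (246.1) and cel-mir-53 (237.7), which belong to the miR-51 family. tRNA genes, transcribed by RNA polymerase III, had 20 of 612 (3.27%, odds ratio 0.670, adjusted p = 0.115), rRNA genes 0 of 20 (upper 95% limit 16.1125%; adjusted p = 0.727), lincRNA genes 10 of 194 (5.15%, adjusted p = 0.736) and other ncRNA genes 326 of 7764 (4.199%, odds ratio 0.869, adjusted p = 0.0578). tRNA genes were occupied less often than protein-coding genes in 4 of 10 alternatives, which were replicate 1 alone (odds ratio 0.393, exact adjusted p = 0.000324), 1000 bp upstream to 200 bp downstream (0.619, 0.0401), whole genes (0.357, 4.84e-05) and the nearest 5′ end only (0.560, 0.0379; range 4.84e-05 to 1). Other ncRNA genes were occupied less often in 6 of 10 alternatives, with an odds ratio of 0.480 over whole genes (exact adjusted p = 8.43e-27, range 8.43e-27 to 1). The whole-gene window runs from 500 bp upstream to the 3′ end, so it grows with gene length. Small noncoding genes thus have shorter windows than most coding genes. Whole-gene odds ratios of noncoding classes cannot be separated from this difference in window length. With the nearest 5′ end only, a noncoding gene had to be nearest among coding and noncoding genes. A coding gene had to be nearest among coding genes only. That rule is stricter for noncoding genes, so a lower occupancy under it cannot be read as theirs. Only 2 of the 20 rRNA genes have a unique window, so their 0 says little. Many of these genes lie in introns or beside coding genes. Without noncoding genes that have a coding 5′ end within 1000 bp, the snRNA, snoRNA and microRNA classes still passed. That filter keeps genes inside introns away from a coding 5′ end, so it does not address them. In replicate 1 alone the odds ratios of the snRNA, snoRNA and microRNA classes were 4.35, 3.42 and 2.35. They were 10.0077, 6.38 and 4.13 in replicate 2 alone, and 2.31, 1.82 and 1.83 over whole genes.

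Summits were richer in G and C than their surroundings and richer in the repeat GAGAGA. GC content within 100 bp of the summit was 40.1%, against 37.4% at 1000 bp to each side, a difference of 2.69 percentage points (SE 0.170 over 1861 peaks, permutation p = 1e-05, the smallest possible). GAGAGA on either strand occurred at 26.3% of summits and 12.8% of windows 1000 bp further along the plus strand. In all, 417 summits had it alone against 167 windows (ratio 2.497, exact McNemar test, adjusted p = 5.96e-25 over 5 motifs). TTTCAG, the splice acceptor consensus, was rarer at summits (27.9% against 33.6%, ratio 0.760, exact adjusted p = 0.000408). The TATA motif TATAAA (16.6% against 18.6%, exact adjusted p = 0.134), the Sp1-like motif GGGCGG (5.53% against 4.14%, 0.0891) and TTTTTT (54% against 56.1%, 0.211) did not pass. In replicate 1 alone GGGCGG passed (ratio 1.81, exact adjusted p = 0.000326, range 0.000326 to 0.339). In replicate 2 alone TATAAA (0.749, 0.0017, range 0.0017 to 0.803) and TTTTTT (0.763, 0.000134, range 0.000134 to 0.715) were rarer at summits.

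The genes farthest toward replicate 1 included neighbours of hsp-90 and hsp-110, and the genes farthest toward replicate 2 included cuticle collagens. At the 1759 matched peaks replicate 1 had a median 2.42 times the signal of replicate 2, and ratios are given relative to that. The largest were at C47E8.11 beside the 3′ part of hsp-90 (centred log2 ratio 3.49), ufbp-1 beside the 3′ end of hsp-110 (3.11), ikke-1 (2.90), R107.5 (2.86) and atfs-1 (2.84), the regulator of the mitochondrial stress response. The smallest were at R02E4.3 (-4.49), the methionine synthase gene metr-1 (-4.35), the collagen genes dpy-4 (-4.15) and sqt-1 (-3.86), and C05G5.7 next to let-7 (-3.87). The ikke-1 summit lay 147 bp past the 3′ end of R107.5, and the R107.5 summit at -124 bp from its 5′ end. Both entries thus flank R107.5. At C47E8.11 the replicate 1 peak (252.7) covers this summit (pooled signal 56.9) and a stronger one (272.2) 22 bp from the 5′ end, where the ratio was 2.67, below that of atfs-1, so that its first place rests on the weaker summit. At promoters, constitutive chaperones had a median of 1.24 (12 of 16 genes above 0, percentile 99.97 among random lists), translation factors 0.88 (7 of 8, 98.7) and ribosomal proteins 0.59 (31 of 43, 99.4). With peaks matched by summits within 100 bp the chaperone median was 0.41 (percentile 78.3) and that of translation factors 0.84 (94.7), and with a lowess trend removed translation factors lay at percentile 97.03. Collagens had a promoter median of 0.15, with 5 genes on each side (percentile 43.2), and 0.91 with summits within 100 bp (94.7). The other lists with at least 5 such genes lay between percentiles 4.34 (glycolysis, median -0.84) and 83.1 (oxidative phosphorylation, 1.16).

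Over whole genes, a measure chosen after seeing the data, heat shock and ribosomal genes lay toward replicate 1 and collagen, molting and muscle genes toward replicate 2. The median ratio over 7041 genes was 1.80, and values are relative to it. Background regions of both replicate lists enter this measure. Inducible heat shock genes had a median of 2.05 (8 of 10 genes above 0, percentile 100 among random lists matched on signal), from -0.77 at hsp-12.6 to 3.75 at F44E5.5. Of these, hsp-16.2 and hsp-16.41 share a peak, and hsp-16.48, F44E5.4 and F44E5.5 are not unique in their promoter windows. Ribosomal proteins had a median of 0.85 (57 of 69, percentile 100) and translation factors 0.89 (20 of 29, 99.98). Cuticle collagens had a median of -0.60 (29 of 39 below 0, percentile 0), with dpy-13 (-5.10), sqt-3 (-3.72), col-90 (-3.67) and dpy-8 (-3.45) lowest. Molting and epidermis genes had a median of -0.73 (18 of 27 below 0, percentile 0.025), with the cuticle-associated gene noah-1 (-3.39), the collagen prolyl hydroxylase gene dpy-18 (-3.21) and the cadherin gene hmr-1 (-2.87) lowest. Muscle genes had a median of -0.38 (27 of 34 below 0, percentile 1.12, and 4.16 when matched on gene length). Constitutive chaperones had a median of 0.46 (18 of 25, percentile 90.8). The other 18 lists lay between percentiles 7.59 (histones) and 93.0 (oxidative phosphorylation).

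**Figure D4:**
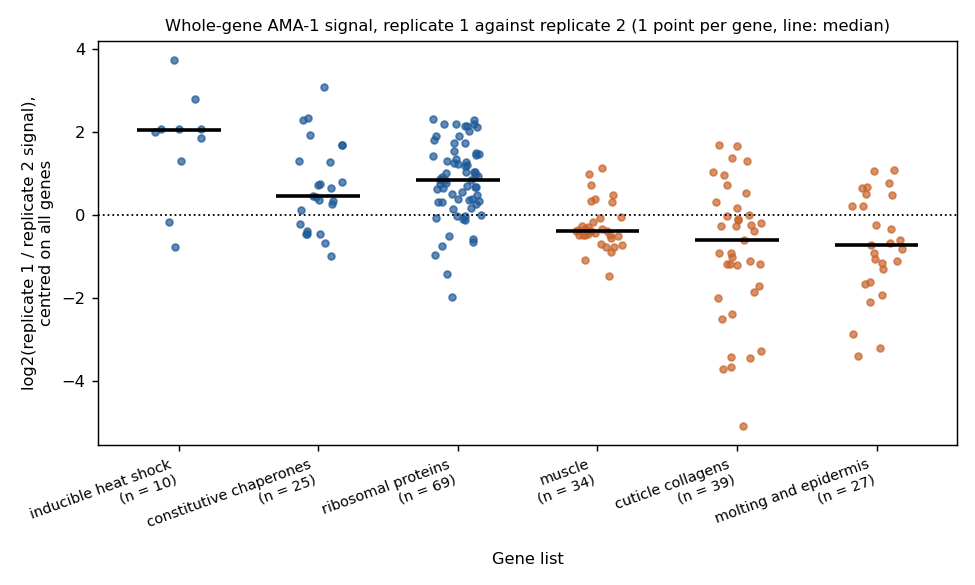
Whole-gene log2 ratio of replicate 1 to replicate 2 signal, centred on all 7041 genes (y axis), for 6 gene lists (x axis), with 1 point per gene and a line at the median. Medians run from 2.05 for inducible heat shock genes to -0.73 for molting and epidermis genes.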

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

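Chosen only after the result was seen were the unique windows, the noncoding genes away from coding 5′ ends and the whole-gene replicate comparison with its settings. Of 654 alternative values, 569 kept their direction and their side of the threshold or lay close to the reported value, 33 reversed, 25 passed a threshold newly, 21 no longer passed and 6 moved. The cause was not tested for any of them. Read depth is not given, so what it limits is unknown here. Ribosomal proteins, constitutive chaperones, V-ATPase, proteasome, oxidative phosphorylation, chemoreceptors and F-box genes kept their occupancy calls in all 10 alternatives, as did X and the autosome centre in 8 and the snRNA, snoRNA and microRNA classes in 10.

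With each replicate left out in turn, odds ratios ranged from 1.35 to 3.59 for histones, 0.463 to 2.69 for molting genes, 0.476 to 1.79 for intestine, 7.36 to 10.4 for heat shock, 2.42 to 5.36 for RNA polymerase II, 0.987 to 3.90 for collagens, 2.26 to 3.18 for muscle and 0.952 to 1.74 for neurons. Lists that kept their calls ranged from 8.59 to 36.6 (ribosomal), 15.7 to 39.1 (chaperones), 5.53 to 20.1 (V-ATPase), 4.58 to 9.13 (proteasome), 4.75 to 8.81 (oxidative phosphorylation) and 0.0788 to 0.219 (F-box). Occupied genes ranged from 587 to 1046. For noncoding classes the ranges were 4.35 to 10.0077 (snRNA), 3.42 to 6.38 (snoRNA), 2.35 to 4.13 (microRNA), 0.393 to 0.887 (tRNA), 0.577 to 1.61 (lincRNA) and 0.818 to 1.13 (ncRNA), and for motifs 0.749 to 0.941 (TATAAA), 0.763 to 1.03 (TTTTTT) and 1.35 to 1.81 (GGGCGG). For list signal they were 1.14 to 1.17 (ribosomal), 0.902 to 1.25 (translation factors), 1.44 to 1.47 (collagens), 0.939 to 1.07 (oxidative phosphorylation), 0.968 to 1.46 (lysozymes) and 0.854 to 0.997 (nuclear hormone receptors).

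Replicate overlap was 29.3% with 50 percent reciprocal overlap and 28.5% with summits within 100 bp. With the 930 peaks of highest signal, 486 genes were occupied and the odds ratios were 1.03 for molting genes, 0.871 for muscle, 0 for neurons, 0 for cell cycle, 0.166 for C-type lectins and 0.844 for lincRNA, and the signal ratios 1.11 for ribosomal proteins and 0.897 for lysozymes. With 250 bp windows the odds ratios were 4.80 for glycolysis, 0.682 for cell cycle and 2.63 for lysozymes, and the signal ratios 1.196 for ribosomal proteins, 0.967 for proteasome and 1.01 for RNA polymerase II. With 1000 bp upstream to 200 bp downstream they were 1.53 for collagens, 2.91 for glycolysis, 0.619 for tRNA and 0.700 for ncRNA, and the signal ratios 1.01 for RNA polymerase II and 0.908 for chemoreceptors. Over whole genes they were 1.66 for collagens, 1.09 for nuclear hormone receptors, 0.357 for tRNA and 0.480 for ncRNA. The tRNA and ncRNA values compare windows of unequal length. The whole-gene signal ratios were 1.23 for ribosomal proteins, 1.08 for oxidative phosphorylation, 1.0998 for glycolysis, 0.897 for chemoreceptors, 0.989 for lysozymes and 0.883 for nuclear hormone receptors.

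With interval overlap the RNA polymerase II signal ratio was 1.02. With the nearest 5′ end only the odds ratios were 2.46 for lysozymes, 0.560 for tRNA and 0.571 for ncRNA, and the signal ratios 1.12 for ribosomal proteins, 0.980 for proteasome, 1.13 for oxidative phosphorylation, 1.02 for RNA polymerase II and 0.913 for chemoreceptors. For tRNA and ncRNA genes that rule was stricter than for coding genes. Among genes with no other 5′ end within 1000 bp the odds ratios were 4.26 for translation factors, 27.8 for histones, 3.66 for muscle, 9.22 for heat shock and 0 for RNA polymerase II, and for noncoding genes away from coding 5′ ends 0.831 (lincRNA) and 0.772 (ncRNA). In unique windows they were 17.99 for histones, 1.71 for collagens, 4.14 for glycolysis and 0.824 for ncRNA. TATAAA had a ratio of 0.822 with flanks at 500 bp. The ribosomal replicate difference was 0.85 over whole genes, matched on signal or on length. Whole-gene percentiles were 4.16 for muscle and 97.6 for chaperones when matched on length, and with ranks 98.1 for proteasome and 98.8 for oxidative phosphorylation.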

Other observations

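Over whole genes, measured in each replicate's 1861 strongest peaks, 14 of 40 molting and epidermis genes had a summit in replicate 2 (odds ratio 10.4, Fisher's exact test, adjusted p = 3.24e-08), and 1 of 40, pdi-2, in replicate 1 (exact adjusted p = 0.673). The 14 were mlt-11, pdi-2, ptr-4, phy-2, noah-2, lin-26, ptr-18, qua-1, wrt-1, hmr-1, lrp-1, nhr-23, dpy-18 and mup-4. Of them nhr-23 encodes a nuclear receptor needed for molting. Heterochronic genes had 5 of 11 in replicate 2 (daf-12, kin-20, lin-14, lin-42 and nhr-85; odds ratio 15.9, exact adjusted p = 0.000409) and 3 of 11 in replicate 1 (daf-12, lin-14 and lin-66; odds ratio 5.39, exact adjusted p = 0.0584). Collagens had 19 and 10 of 174. These are long genes (median 5350 bp for molting and 7697 bp for heterochronic genes). Against random lists matched on gene length the replicate 2 counts stayed high, 14 against a mean of 3.05 (permutation adjusted p = 0.00104) and 5 against 1.097 (permutation adjusted p = 0.0110). Matched on length, heterochronic genes did not lie toward either replicate (percentile 47.6). The difference between replicates in these counts was not tested, and the counts were chosen after seeing the data.

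Chosen only after the result was seen were the tests of heat shock peaks in both replicates, of summits in heat shock gene bodies, of the heat shock and molting lists over whole genes, of molting genes against the collagens and of the collagens matched on gene length. The design has 1 group and names no biological difference between the replicates, so the biological explanations below are hypotheses found and tested on the same data.

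Replicate 2 had more summits in gene bodies than replicate 1, by 18.9 percentage points. A background spread evenly over exonic sequence is argued against, since 0.425% of its exonic gene-body summits (95% interval 0.117 to 1.53%) lay in chemoreceptor exons, which hold 4.002% of exon bases. Chemoreceptors were low in occupancy under every setting, so the test cannot decide on a background that avoids them too. Weaker enrichment in replicate 2 may remain, because among the 200 strongest peaks of each replicate the difference was 5 points (95% interval -4.13 to 14.1, Fisher's exact test p = 0.335), an interval too wide to decide.

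Inducible heat shock genes were occupied with no heat treatment in the labels. In the body or past the 3′ end, 8 of 11 heat shock genes had a summit. Among genes unique in sequence both there and in the promoter window, without summits near an snRNA gene as at hsp-12.3, 4 of 6 did, against 4.55% of other genes (odds ratio 41.9, Fisher's exact test p = 6.07e-05). These 4 were the genes already called occupied, while most of the other genes had no promoter summit. Because occupied genes were not the control, the test cannot decide whether open promoter background without transcription explains the occupancy. Peaks in one replicate only stay open for the promoter call, because 2 of the 4 occupied genes, which share 1 peak, had a peak in both replicates. Over whole genes the list passed in replicate 2 alone (3 of 11, exact adjusted p = 0.0328) and in replicate 1 alone (4 of 11, 0.00887). The replicate 2 genes were hsp-16.2 and hsp-16.41, which share a peak, and hsp-12.3, whose peak lies beside an snRNA gene. Both p-values count the shared peak for each of its genes, so they do not settle the question. Over whole genes the list lay toward replicate 1 at percentile 100 of lists matched on signal, and also at percentile 100 matched on gene length, which argues against short genes in general. A hypothesis is that the larvae of replicate 1 may have had a stronger heat shock response, from handling or growth conditions not given in the sources used here. The lean was not particular to heat shock genes, since ribosomal proteins (57 of 69 genes, percentile 100) and translation factors (99.98) also lay toward replicate 1.

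Cuticle collagens were occupied at 18 of 174 promoters in replicate 2 and 9 in replicate 1, a difference that was not tested, and over whole genes, though not at promoters, they lay toward replicate 2. Short genes in general are argued against as the reason that collagens lie toward replicate 2, since over whole genes, matched on gene length, 29 of 39 lay below 0 and the median was at percentile 0. Molting genes lay toward replicate 2 over their whole length at percentile 0.025, and at 0.455 when matched on gene length, which argues against long genes in general. At promoters only 1 molting gene had a matched peak, so that a different time in the molting cycle was not decided there. These whole-gene values include peaks near background in one or both replicates. A hypothesis is that the larvae of replicate 2 may have been collected at another time in the molting cycle. The lean was not particular to molting genes, since muscle genes also lay toward replicate 2 (27 of 34, percentile 1.12, and 4.16 matched on gene length).

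Genes starting 50 to 300 bp behind a same-strand gene were occupied in 4.55% against 4.83% of other genes (odds ratio 0.939, Fisher's exact test p = 0.604), which meets the limit written beforehand against a lower occupancy, but a p above 0.05 shows no absence of one and it stays undecided. The share of summits within 500 bp of a 3′ end, 33.1%, lay above every one of 1000 shifts. Chemoreceptors kept an odds ratio of 0.0734 among genes with unique windows.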
